A study of Mus musculus with 24 samples.

How the data were processed

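Total RNA from hearts of C57BL/6J mice, extracted with Trizol and labelled as biotinylated cRNA for Affymetrix arrays per the labels' protocols, was measured in 24 samples. Groups came from the sample titles and treatment labels: sham operation or MCAO, each at 24 h and 72 h, with 6 arrays per group numbered 1 to 6. The free-text description of the 72 h samples names 24 h, against their titles, source names and time labels, which were followed. The labels describe groups of animals without stating that each array is a separate animal, so p-values measure the spread between these samples.

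The deposited table holds log2 values for 24973 gene identifiers, with no missing values, a lowest value of 2.78, a median of 4.16 and a highest of 13.5. The log2 base was inferred from the values: the highest would be 11531 on a linear scale, whereas as a natural log it would be 724506, above what a scanner records. The deposited values had been quantile-normalized by the authors, as judged from the values: the sorted values were identical in 23 columns and differed by at most 0.00191 in MCAO 24 h replicate 1. The summarization method, software and genome build are not given in the sources used here; the submitters' processing notes name HOMER, without a version or role. No background signal of the arrays was analysed here, so low values carry no detection limit. The level that most olfactory and vomeronasal receptor genes stay under was used once in its place, a choice made after the data were examined.

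Of the identifiers, 24015 had 1 gene symbol in the platform annotation used here, 0 had several and 958 were unnamed here. For 4 symbols with several identifiers the one with the highest mean was kept, which left 24011 genes. No coordinates are given. Genes were tested with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, default settings, 4 group means, all 24 arrays, 20 residual degrees of freedom) with Benjamini-Hochberg adjustment at 0.05. Contrasts were MCAO against sham at each time, their difference, and sham at 72 h against 24 h. Standard errors are moderated. Adjusted p-values in the text are limma's unless another test is named.

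There were 35 gene lists with 701 genes, 642 of them measured, fixed before the data were examined along with the design, the other settings listed here and the rule for named genes. The lists held 728 entries, since some genes belong to several of them. The 34 lists with at least 5 measured members were tested with camera (two-sided, preset correlation 0.01), and with an estimated correlation and fry as alternatives. The rule named the 10 highest and 10 lowest log2 changes among genes past the threshold for each MCAO contrast, and 5 and 5 for the other contrasts, leaving out predicted or unnamed symbols, plus up to 4 members with the smallest p of each list described. The sex-linked list, with 4 measured members, served only to check the mix of animals: 24 of 24 arrays showed the same pattern. The olfactory and vomeronasal receptor genes and the means of list genes per array were chosen after the data were examined and were compared with exact permutation tests over 924 splits.

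Alternatives were a trended and robust prior, quantile normalization on top, median centring, a filter on dim genes, the mean of identifiers, every identifier as its own row, array weights, the replicate number as a block, leaving out each array, and fitting only the groups compared. Added after the data were examined were fits without MCAO 24 h replicates 5 and 6, without sham 24 h replicate 5 and sham 72 h replicate 3, and with the first principal component of the receptor genes as a covariate, and list tests without each array. The fit was tested on simulated data with 200 changed genes among 24011: at 24 h, 73.1% of log2 changes of 0.5 and 98.5% of changes of 1 were recovered, at 72 h 62.7% and 97.0%, for the difference between times 50.7% and 89.6%, and for the sham contrast 74.6% and 98.5%. Of the simulated calls, 7.65% at 24 h, 4.95% at 72 h, 5.88% for the difference and 4.21% for the sham contrast were of unchanged genes. The simulated noise was normal, independent between genes and of the same SD per gene in all groups. In the real data the median residual SD was 0.192 in the 24 h groups and 0.116 in the 72 h groups. The simulated shares therefore need not hold at either time. No columns were left unused.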

Results

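Hearts of 8-week-old C57BL/6J mice were profiled on Affymetrix arrays 24 h and 72 h after occlusion of the middle cerebral artery (MCAO), which causes an ischemic stroke of the brain, or after a sham operation. The question put to the data was how stroke in the brain alters gene expression in the heart at each time. The 24 arrays formed 4 groups of 6, and 24011 named genes were compared on the deposited log2 scale. The number of arrays limits the precision. Arrays correlated with the rest of their own group at a mean r across genes of 0.993 (SD 0.000301, n = 6) for MCAO 72 h, 0.991 (SD 0.00189, n = 6) for sham 72 h and 0.989 (SD 0.00358, n = 6) for sham 24 h, against 0.974 (SD 0.00726, n = 6) for MCAO 24 h. Within MCAO 24 h, replicates 5 and 6 had the lowest values, 0.968 and 0.963.

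At 24 h after MCAO, Fkbp5 (Entrez Gene 14229), a co-chaperone of the glucocorticoid receptor and a direct target of it, rose most among named genes. It went from 5.29 ± 0.61 in sham hearts to 8.56 ± 0.55 (log2, mean ± SD, n = 6 each), which is 9.66-fold (log2 change 3.27, SE 0.32, adjusted p = 6.45e-07) seen in 6 of 6 MCAO arrays. Nr4a1, an immediate-early nuclear receptor, rose 5.20-fold, the kinase gene Map3k6 4.38-fold, the steroid sulfate transporter gene Slc10a6 4.16-fold and the desaturase gene Scd4 4.13-fold. Arrdc2, Snord1b, Depp1, Car4 and Cdkn1a, the last encoding the cell cycle inhibitor p21, rose between 3.38-fold and 3.85-fold. Among genes that fell, Itgb6 (integrin beta 6) was 4.61-fold lower, Aplnr (the apelin receptor) 4.02-fold lower, Tuba4a 3.49-fold lower, Lmod3 (a leiomodin of muscle thin filaments) 3.17-fold lower and Col3a1 (type III collagen) 3.09-fold lower. Sft2d1, Lce1j and the immunoglobulin or T cell receptor joining segments Igkj5, Trbj1-6 and Trdj1 also fell, between 2.88-fold and 4.64-fold.

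In total 2654 genes rose and 2583 fell at 24 h, of which 115 and 91 changed at least 2-fold. The count was 5237 in the fit of all 24 arrays but 2194 when only the 12 arrays of this time were fitted, 3259 with array weights and 3441 after dim genes were left out. Both fits called 2187 genes. Igkj5 (adjusted p = 0.0506) and Trbj1-6 (adjusted p = 0.0684) were lost there. Among 1370 olfactory and vomeronasal receptor genes, which serve chemical sensing in the nose, 159 (11.6%) also passed at 24 h. Their differences from the sham mean had a larger SD per array in MCAO 24 h (0.239 ± 0.0565 log2, n = 6) than in sham 24 h (0.116 ± 0.0156, n = 6, exact permutation test, two-sided, p = 0.00216, adjusted p = 0.00649 over 9 tests).

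Genes of the glucocorticoid response moved together at 24 h. Of 21 measured members 12 rose and 0 fell (15 rose adjusted over the list alone). Their median log2 change was 0.68 (camera adjusted p = 3.21e-09, adjusted p = 0.0193 with an estimated correlation). Besides Fkbp5 they included the clock gene Per1 (log2 change 1.59, SE 0.22), Klf15 (1.17, SE 0.16), a regulator of amino acid and lipid use in heart, and the metallothionein Mt1 (0.66, SE 0.10). The list of muscle atrophy, autophagy and FoxO targets had 7 of 18 members up and 0 down (8 up adjusted over the list alone, camera adjusted p = 0.00117, adjusted p = 0.0851 with an estimated correlation). They included the mitophagy gene Bnip3 (1.56, SE 0.16), the lysosomal protease gene Ctsl (0.71, SE 0.11) and Fbxo32 (0.68, SE 0.13), which encodes the ubiquitin ligase atrogin-1. Of 15 adipocyte markers 7 rose and 0 fell (7 adjusted over the list alone, camera adjusted p = 0.00469, adjusted p = 0.256 with an estimated correlation). The members that rose, such as the triglyceride lipase gene Pnpla2 (1.14, SE 0.09), Pparg (0.68, SE 0.10) and the lipid droplet gene Plin4 (0.92, SE 0.15), are also expressed outside fat cells. Of 18 genes of fatty acid use 5 rose and 0 fell (5 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00557, adjusted p = 0.659 with an estimated correlation). Acot1 (1.70, SE 0.33), Plin5 (0.80, SE 0.16) and the fatty acid transporter gene Cd36 (0.27, SE 0.05) were among them. That list did not pass without MCAO 24 h replicate 6 (adjusted p = 0.0701) or without replicates 5 and 6 (adjusted p = 0.0577).

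Other lists were lower at 24 h. Of 31 extracellular matrix genes 11 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 0.00117, adjusted p = 0.659 with an estimated correlation). The small proteoglycan gene Lum (log2 change -1.31, SE 0.21), the collagen chaperone gene Serpinh1 (-1.13, SE 0.19), Col3a1 (-1.63, SE 0.31) and Col5a1 (-0.90, SE 0.19) had the smallest p. Of 25 calcium handling and ion channel genes 9 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.000183, adjusted p = 0.0851 with an estimated correlation). Gja1, which encodes the main ventricular gap junction protein, fell by 1.12 (SE 0.11), the calcium store gene Casq2 fell by 0.53 (SE 0.07) and the potassium channel subunit gene Kcne1 fell by 0.92 (SE 0.15). Of 12 genes of MHC class II and antigen presentation 6 fell and 0 rose (6 adjusted over the list alone, camera adjusted p = 0.00525, adjusted p = 0.464 with an estimated correlation). Members that fell included H2-Eb1 (-1.12, SE 0.17), H2-Ab1 (-1.11, SE 0.26) and the invariant chain gene Cd74 (-0.80, SE 0.21). These 7 of 34 lists passed with the preset correlation and 1, the glucocorticoid response, with an estimated correlation. With the first principal component of the olfactory and vomeronasal receptor genes as a covariate, 319 genes passed at 24 h, 188 of them among the 5237. Of the 20 genes with the largest changes 6 passed there (Fkbp5, Nr4a1, Map3k6, Itgb6, Aplnr and Tuba4a) and 14 did not, and the median SE of these 14 went from 0.311 to 0.468. Among the 14, 6 had a log2 change within 1.5 times the first one, such as Col3a1 (-1.63, SE 0.31, to -2.14, SE 0.55) and Scd4 (2.04, SE 0.36, to 1.70, SE 0.66). Another 7 had a smaller change of the same sign, such as Cdkn1a (1.76, SE 0.31, to 0.59, SE 0.50), and Igkj5 changed sign (-1.82, SE 0.41, to 0.69, SE 0.41, adjusted p = 0.414). The list of fatty acid use (adjusted p = 0.294) and that of calcium handling and ion channels (adjusted p = 0.392) then lost their calls. Their median log2 changes went from 0.29 to 0.16 and from -0.25 to -0.03, while Gja1 (-0.94, adjusted p = 0.0233) and Casq2 (-0.64, adjusted p = 0.0202) passed in that fit too. The glucocorticoid response list passed there as well (median 0.73, adjusted p = 2.76e-07). Atrial markers (upward, adjusted p = 0.000559), immediate-early and adrenergic genes (upward, adjusted p = 0.00353) and cell cycle genes (downward, adjusted p = 0.0179) passed in addition, so that 8 lists passed in that fit. In the fit without the covariate, 9 of 100 splits of the 12 arrays gave at least 7 lists with the preset correlation. Atrial markers averaged 0.57 ± 0.91 above the sham mean in MCAO 24 h and -0.28 ± 0.29 in sham 24 h (log2, n = 6 each, exact permutation test, two-sided, p = 0.0238, adjusted p = 0.0536). Replicate 1 of MCAO 24 h lay at 2.31. Sham 72 h averaged 0.28 ± 0.78 and MCAO 72 h 0.37 ± 0.78 (log2, n = 6 each), so sham 24 h was the lowest group. Single arrays were high at 72 h too, sham replicate 6 at 1.55 and MCAO replicate 5 at 1.90.

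At 72 h, Lcn2 (Entrez Gene 16819), which encodes the acute phase protein lipocalin 2, was 8.45-fold higher after MCAO (from 8.00 ± 0.59 to 11.08 ± 0.71 log2, mean ± SD, n = 6 each; log2 change 3.08, SE 0.42, adjusted p = 0.000129). Myh7 (Entrez Gene 140781), the slow beta myosin heavy chain, was 8.38-fold higher (from 8.73 ± 0.47 to 11.80 ± 0.34, n = 6 each; log2 change 3.07, SE 0.35, adjusted p = 1.95e-05). Both were higher in 6 of 6 MCAO arrays. Fkbp5 rose 4.77-fold, Cdkn1a 3.33-fold, Scd4 3.19-fold, the p53 target Trp53inp1 3.07-fold and Ddit4, an inhibitor of mTORC1 signalling, 3.05-fold, followed by Spock2, Fam107a and Map3k6 between 2.75-fold and 2.91-fold. Itgb6 was 3.87-fold lower, Lmod3 3.05-fold, Aplnr 2.91-fold, Cmss1 2.78-fold and Col3a1 2.73-fold lower. Sh3bgr, the MHC class II gene H2-Ab1, Folr2 (a marker of resident macrophages), the histone gene H2bc7 and the ketone body enzyme gene Bdh1 fell between 2.23-fold and 2.48-fold. In total 280 genes rose and 285 fell, of which 29 and 18 changed at least 2-fold. The count of 565 became 1410 when only the 12 arrays of this time were fitted, 1905 with array weights and 1103 without MCAO 24 h replicates 5 and 6. Both fits called 555 genes. H2bc7 lost its call (highest adjusted p = 0.0820) when any of 6 arrays was left out. Of the olfactory and vomeronasal receptor genes 1 passed at 72 h.

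**Figure D1:**
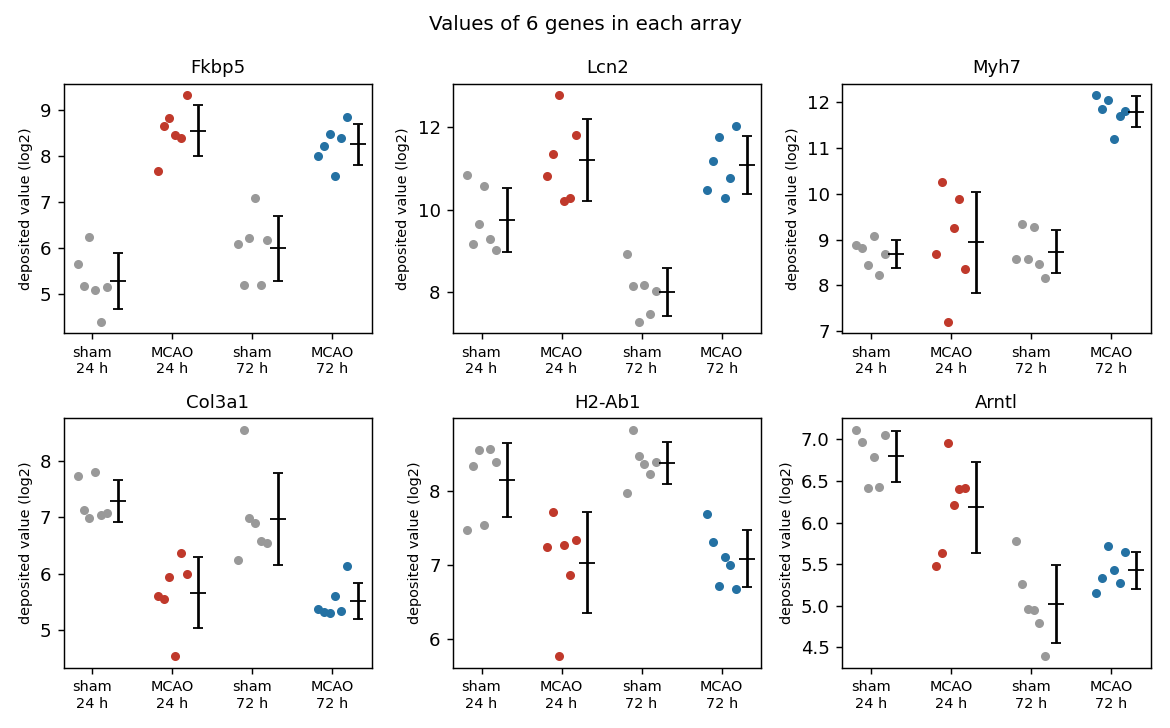
Deposited log2 values of 6 genes in each of the 24 arrays, by group, with 1 point per array; the bar beside each group is the mean and its SD (n = 6). Fkbp5 was higher after MCAO at both times, Myh7 rose from 8.73 to 11.80 at 72 h, Col3a1 and H2-Ab1 were lower after MCAO, and Arntl was lower in sham hearts at 72 h than at 24 h.

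At 72 h the glucocorticoid response list again had 12 of 21 members up and 0 down (17 up adjusted over the list alone; median log2 change 0.67, camera adjusted p = 4.08e-24, adjusted p = 6.50e-05 with an estimated correlation). Sgk1 (0.62, SE 0.11) was among them. Bnip3 (1.16, SE 0.16), Cited2 (0.59, SE 0.10) and Fbxo32 (0.52, SE 0.13) rose among atrophy, autophagy and FoxO targets. That made 3 of 18, and 0 fell (6 up adjusted over the list alone, camera adjusted p = 4.39e-07, adjusted p = 0.00722 with an estimated correlation). Of 15 adipocyte markers 5 rose and 0 fell (6 adjusted over the list alone, camera adjusted p = 4.00e-05, adjusted p = 0.0427 with an estimated correlation). Pnpla2 (0.81, SE 0.09) and Plin4 (0.89, SE 0.15) had the smallest p. Of 18 genes of fatty acid use 3 rose, Decr1 (0.44, SE 0.10), Acot2 (0.66, SE 0.17) and Cd36 (0.20, SE 0.05), and 0 fell (9 adjusted over the list alone, camera adjusted p = 1.26e-07, adjusted p = 0.119 with an estimated correlation). Endoplasmic reticulum stress genes had 2 of 21 members up, Dnajc3 (0.40, SE 0.09) and Atf6 (0.44, SE 0.11), and 0 down (5 up adjusted over the list alone, camera adjusted p = 3.91e-05, adjusted p = 0.178 with an estimated correlation). Of 20 oxidative stress genes 6 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.00321, adjusted p = 0.0821 with an estimated correlation). Examples were the quinone reductase gene Nqo1 at 0.71 (SE 0.12) and the mitochondrial superoxide dismutase gene Sod2 at -0.30 (SE 0.05). Immediate-early and adrenergic genes had 1 of 24 members up, Zfp36 (0.90, SE 0.20, 4 adjusted over the list alone, camera adjusted p = 0.000338, adjusted p = 0.0701 with an estimated correlation). Acute phase genes had 1 of 25 up, Lcn2 (5 adjusted over the list alone, camera adjusted p = 0.00137, adjusted p = 0.253 with an estimated correlation). Lcn2 also belongs to the glucocorticoid response list, so the acute phase list is not separate from it. In the immediate-early and adrenergic list and in the acute phase list 0 members fell.

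Oxidative phosphorylation genes were lower at 72 h, with 6 of 31 members down and 0 up (8 down adjusted over the list alone, camera adjusted p = 2.33e-09, adjusted p = 0.0427 with an estimated correlation). Uqcrc2 (-0.32, SE 0.05) and Uqcrfs1 (-0.42, SE 0.09) of complex III and Ndufv2 (-0.31, SE 0.07) and Ndufs4 (-0.47, SE 0.10) of complex I had the smallest p. Of 25 calcium handling and ion channel genes 3 fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 7.61e-05, adjusted p = 0.0427 with an estimated correlation). Those that fell were Casq2 (-0.39, SE 0.07) and the transient outward current genes Kcnd2 (-0.88, SE 0.20) and Kcnip2 (-0.66, SE 0.17). Kcna5 rose (0.56, SE 0.14). Of 12 genes of MHC class II and antigen presentation 3 fell and 0 rose (4 adjusted over the list alone, camera adjusted p = 1.62e-05, adjusted p = 0.0975 with an estimated correlation). These were H2-Ab1 (-1.29, SE 0.26), Cd74 (-1.02, SE 0.21) and H2-Eb1 (-0.64, SE 0.17). Of 15 B cell markers 1 fell, Ighm (-0.84, SE 0.21), and 0 rose (2 adjusted over the list alone, camera adjusted p = 0.00400, adjusted p = 0.0406 with an estimated correlation). Of 24 monocyte and macrophage markers 2 fell, Folr2 (-1.21, SE 0.22) and Cbr2 (-0.84, SE 0.22), and 1 rose, the efferocytosis receptor gene Mertk (0.57, SE 0.10). The counts were 5 and 1 adjusted over the list alone (camera adjusted p = 0.00388, adjusted p = 0.364 with an estimated correlation). Of 31 extracellular matrix genes 2 fell, Col3a1 (-1.45, SE 0.31) and Serpinh1 (-0.78, SE 0.19), and 0 rose (8 down and 1 up adjusted over the list alone, camera adjusted p = 0.000165, adjusted p = 0.420 with an estimated correlation). Without sham 72 h replicate 2, neither the extracellular matrix list (adjusted p = 0.206) nor the monocyte and macrophage list (adjusted p = 0.10) passed.

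Of 25 interferon response genes 1 fell, Bst2 (-0.98, SE 0.21), and 0 rose (2 down adjusted over the list alone; median log2 change -0.35, camera adjusted p = 2.53e-08, adjusted p = 0.178 with an estimated correlation). The cell cycle list was lower as a list with 0 of 31 members past the threshold (0 adjusted over the list alone, camera adjusted p = 7.61e-05, adjusted p = 0.253 with an estimated correlation). So was that of chemokines and leukocyte adhesion with 0 of 24 (3 down adjusted over the list alone, camera adjusted p = 0.00321, adjusted p = 0.119 with an estimated correlation). In all, 17 of 34 lists passed at 72 h, 8 upward and 9 downward, and 6 of them with an estimated correlation. Of the list members taken by the naming rule at 72 h, single arrays left out ended the calls of H2-Eb1 (12 of 24 arrays), Cd36, Cbr2, Kcnip2 and Hsph1 (9 each), Fbxo32 and Pi16 (8 each), Acot2 and Ighm (7 each), Atf6 and Kcna5 (6 each), Serpinh1 (5), Per1 and Des (3 each), Decr1 and Ccn2 (2 each), and Gsn and Lipe (1 each). In sham 72 h, replicate 2 had the highest Bst2, Ifit1, Ccl12, Fcgr1, Top2a, Prc1, Col1a1 and Col3a1 of its group, by a gap to the next array that passed Dixon's test. Without that array 4 of the 17 lists did not pass, among them cell cycle (adjusted p = 0.10) and chemokines and leukocyte adhesion (adjusted p = 0.0958).

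**Figure D2:**
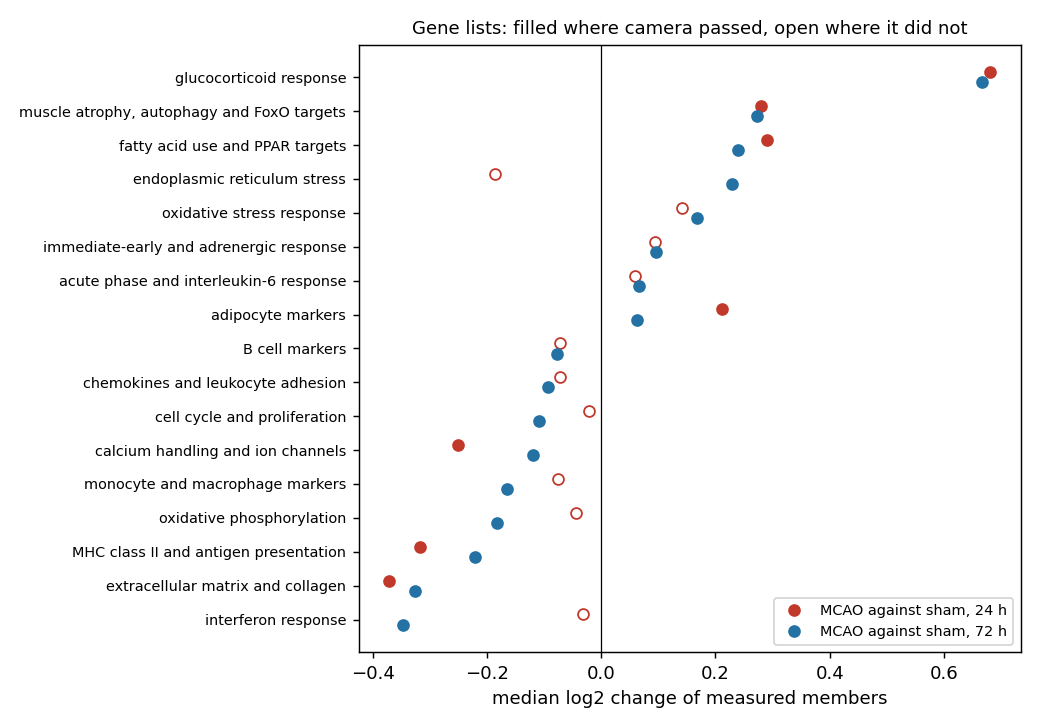
Median log2 change of the measured members of each gene list that passed camera at either time, MCAO minus sham, at 24 h and at 72 h. Filled points passed at an adjusted p of 0.05 with the preset correlation and open points did not; the glucocorticoid response list lay at 0.68 and 0.67.

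The same genes tended to move at both times, in log2 changes that shared no arrays. Across all 24011 genes the log2 changes at 24 h and 72 h correlated with Pearson r = 0.493 and Spearman rho = 0.328 (across genes, which are not independent replicates). Both comparisons called 219 genes higher, where independent lists of these sizes would share 30.9, and 154 lower, where 30.7 would be shared. Another 3 genes were called in opposite directions. The calls at both times used a shared estimate of the spread of each gene. The lists were therefore not independent, and the counts for independent lists are only a rough guide. Fkbp5, Map3k6, Scd4 and Cdkn1a were among the highest and Itgb6, Aplnr, Lmod3 and Col3a1 among the lowest of both.

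**Figure D3:**
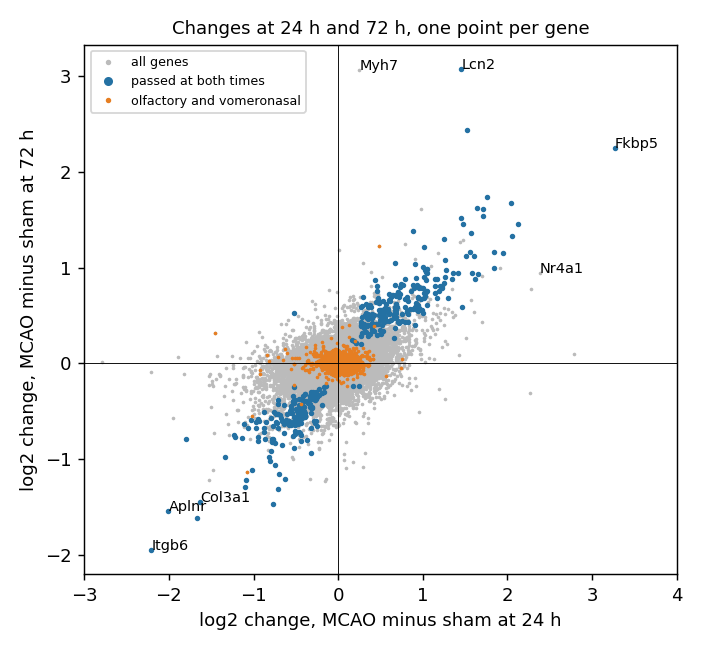
Log2 change at 72 h against log2 change at 24 h, MCAO minus sham, with 1 point per gene; blue points passed at both times and orange points are olfactory and vomeronasal receptor genes. Most of the blue points lie in the quadrants where both changes have the same sign, and the orange ones spread along the 24 h axis.

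The size of the MCAO effect differed between the times for 430 genes, more positive at 72 h for 238 and more negative for 192. Myh7 differed most among named genes, with an effect larger by 2.82 (log2, SE 0.49, adjusted p = 0.00713). At 24 h it was 8.94 ± 1.11 after MCAO and 8.69 ± 0.31 after sham operation (log2, n = 6 each). Lce1j (1.96, SE 0.50), Mir3473d (1.50, SE 0.29), Trdj1 (1.30, SE 0.27) and an immunoglobulin kappa variable segment (1.29, SE 0.23) were also more positive at 72 h. The effect was more negative at 72 h for the nuclear receptor gene Nr4a3 (-1.46, SE 0.32), the clock output gene Dbp (-1.38, SE 0.33), Snora81 (-1.35, SE 0.29), the alcohol dehydrogenase gene Adh1 (-1.27, SE 0.32) and the mitochondrial gene Higd1a (-1.25, SE 0.21). Dbp was itself higher by 1.50 (log2) in sham 72 h than in sham 24 h, a change larger in size than the difference of -1.38. Dbp was also lower after MCAO than after sham operation at 72 h (-1.09, adjusted p = 0.00908). The difference between times alone cannot tell whether the sham or the MCAO groups account for its entry. The count of 430 rose by over 1.5 times without MCAO 24 h replicate 1 (1012) or 6 (858), and to 1079 without MCAO 24 h replicates 5 and 6. It fell by over 1.5 times without MCAO 72 h replicate 2 (233), 3 (197), 4 (250) or 5 (260), sham 24 h replicate 4 (212) or 5 (268), or sham 72 h replicate 1 (267), 2 (264), 4 (209) or 6 (203), and was 219 after dim genes were left out. With the first principal component of the olfactory and vomeronasal receptor genes as a covariate 5 genes passed, 0 of them among the 430. The 10 named genes lost their calls there, and their median SE went from 0.305 to 0.436. For 8 of them the difference stayed within 1.5 times the first one, such as Myh7 (3.61, SE 0.68, adjusted p = 0.0699) and Snora81 (-1.35, SE 0.43), and for 2 it was smaller, Trdj1 (0.34, SE 0.27) and the immunoglobulin kappa variable segment (0.75, SE 0.30). Lce1j, Dbp and Adh1 lost their calls when 20, 7 and 17 of the 24 arrays, respectively, were left out in turn.

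Between the sham groups 5 genes passed, and 4 of them belong to the circadian clock. Arntl, the core clock activator gene also known as Bmal1, was 3.42-fold lower at 72 h than at 24 h (from 6.80 ± 0.31 to 5.02 ± 0.47 log2, n = 6 each; log2 change -1.78, SE 0.22, adjusted p = 0.000791) and its partner-type activator gene Npas2 1.83-fold lower. Dbp was 2.82-fold and Per3 2.03-fold higher. The fifth, Spon2, was 1.50-fold lower. Each was shifted in 6 of 6 arrays. At an unadjusted p under 0.05, 885 genes differed. Only Arntl passed when the 12 sham arrays were fitted alone, and with the replicate number as a block 1 gene passed. The count was 1 without sham 24 h replicate 2 or sham 72 h replicate 6, 3 without sham 24 h replicate 1, 4 or 6 or sham 72 h replicate 3, 4 or 5, and 27 with array weights. Leaving out each array in turn ended the call of Per3 in 18 of 24 cases, of Npas2 in 9, and of Dbp and Spon2 in 2 each. The circadian clock list had 2 of 17 members up and 2 down (9 and 3 adjusted over the list alone, camera adjusted p = 8.10e-07, adjusted p = 0.00395 with an estimated correlation). The glucocorticoid response list had 0 of 21 members past the threshold over all genes (2 up and 3 down adjusted over the list alone; median log2 change 0.06, mean -0.06, camera adjusted p = 0.557).

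**Figure D4:**
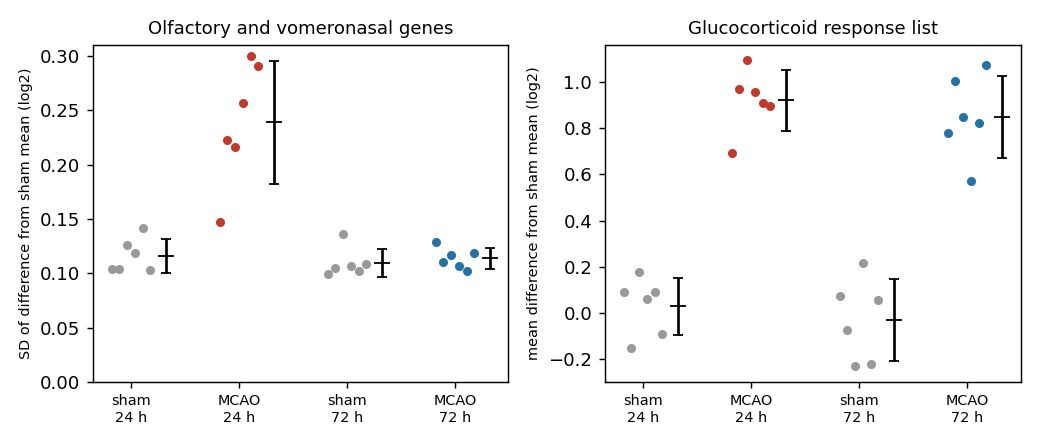
Left, SD over 1370 olfactory and vomeronasal receptor genes of each array's difference from the mean of the sham arrays (log2); right, mean difference of the glucocorticoid response list from the sham mean (log2), with 1 point per array and the mean and SD of each group (n = 6) beside it. The SD was 0.239 on average in MCAO 24 h and between 0.109 and 0.116 in the other groups, whereas the glucocorticoid list was raised in both MCAO groups.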

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

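All tests of explanations in this part were chosen after the result was seen, except the test of a larger response at 24 h and the counts of splits.

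More genes passed at 24 h than at 72 h, 5237 against 565, but the gap was 2194 against 1410 with only the groups compared, 3259 against 1905 with array weights, and reversed, 319 against 672, with the first principal component of the receptor genes as a covariate. The tables argue against MCAO 24 h replicates 5 and 6 as the reason, since 5856 genes passed without them, against 1103 at 72 h in that fit. A shift of the MCAO 24 h arrays that does not depend on expression in the heart may account for part of the count: 11.6% of olfactory and vomeronasal receptor genes passed at 24 h, 0.0730% at 72 h and 21.8% of all genes at 24 h; the component follows the group, so that fit cannot separate the shift from a response. A larger response of the same genes remains open: the genes past the threshold at 72 h had a median change of 0.43 at 24 h, signed by their direction at 72 h, and of 0.55 at 72 h, where they were chosen. RNA quality, array batch and stroke biology at 24 h were not tested apart.

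Myh7 was higher at 72 h, with an MCAO effect larger by 2.82 (log2) than at 24 h. A stretch or hypertrophy programme stays open, since its list without Myh7 differed by 0.0713 on average (95% interval up to 0.35, exact permutation p = 0.543). Its members went both ways, with 2 up, Ccn2 (1.05) among them, and 2 down, Acta1 (-0.98) among them, of 16 adjusted over the list alone. The mean of Nppa, Nppb, Acta1 and Ankrd1 differed by -0.23 at 72 h (95% interval -0.63 to 0.17, exact permutation p = 0.162). As a set, these markers showed no rise beside that of Myh7. Slow skeletal muscle in the tissue stays open too, as its troponin genes Tnnt1 (4.71 in sham and 4.35 in MCAO) and Tnni1 (4.22 and 4.32), with a mean change of -0.13 (exact permutation p = 0.121), lay within 2-fold of 3.96, the 95th percentile of receptor genes (log2). Lower thyroid hormone action is a further hypothesis that stays open: genes known to be induced by the hormone in heart, less the repressed Pln and without Myh7, differed by -0.26 between MCAO and sham (exact permutation test, p = 0.00216, the smallest that 924 splits can give; adjusted p = 0.0130 over 18 tests). At 24 h that difference was -0.18 (exact permutation p = 0.0693), so the index alone does not set the times apart, and no hormone was measured. The induced genes chosen for the index were Myh6, Atp2a2, Kcnd2, Hcn2, Adrb1, Thrsp, Me1 and Slc2a4. Of these, Kcnd2 (-0.88) had already passed at 72 h, and its value in sham 72 h replicate 6 stood apart by Dixon's test (0.706). The test of the index is therefore not independent of the results it is set beside.

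The glucocorticoid response list was higher at both times. The shift of the MCAO 24 h arrays is argued against as the whole source of the rise at 24 h: list members' changes at 24 h and 72 h correlated at r = 0.762, across genes, against 0.493 over all genes. The value of 0.0997 for the receptor genes is a weak comparison, since 1 of these 1370 genes passed at 72 h and r had little room to be high. Time of day of collection stays open: the list mean differed by -0.0596 (95% half-width 0.23) between the sham groups, whose clock genes differed, but members went both ways there, with 2 up and 3 down adjusted over the list alone. The lowest MCAO array lay 0.36 above the highest sham array (log2). Release of stress hormone after stroke is a hypothesis consistent with these values, and steroid or analgesic treatment that differed between the operations remains untested.

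Chance was unlikely as the source of the gene counts by 100 splits each of the samples. In each, 1 split, the real one, gave as many genes, the smallest share that 100 splits can give. The counts were 5237 against at most 425 at 24 h, 565 against at most 38 at 72 h, 430 against at most 19 for the difference between times, and 5 against at most 1 between the sham groups. The sham count was small, and it was 1 with only the sham groups fitted. The correlation of 0.493 was also reached by 1 split, with 0.356 the highest other. For the lists with the preset correlation, 3 of 100 splits gave at least 17 at 72 h (highest other 19), but 9 gave at least 7 at 24 h (highest other 9), so chance was not excluded for the list count at 24 h.

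In 28 of 296 pairs of a named gene and a group (9.46%, where chance gives about 1 in 20), the array farthest out stood apart by Dixon's test for 6 samples (gap over range above 0.625). For sham 72 h replicate 2 this held for Col3a1 (0.677), Ccl12 (0.817), Bst2 (0.670), Ifit1 (0.665), Col1a1 (0.682), Top2a (0.761), Prc1 (0.673) and Fcgr1 (0.854). For MCAO 24 h replicate 1 this held for Arrdc2 (0.683), Pnpla2 (0.682) and the mean of atrial markers (0.627). For MCAO 72 h replicate 3 this held for Hadha (0.638), Cxcl12 (0.688) and Dnajb11 (0.657). For sham 24 h replicate 5 this held for Car4 (0.673), Lce1j (0.669) and Trbj1-6 (0.845). For sham 72 h replicate 3 this held for Zfp36 (0.635), Uqcrfs1 (0.693) and the SD over receptor genes (0.759). For MCAO 72 h replicate 4 this held for Map3k6 (0.768) and Osmr (0.686). For MCAO 72 h replicate 6 this held for Col3a1 (0.644) and Col1a1 (0.657). For sham 72 h replicate 1 this held for Txnip (0.639) and Nqo1 (0.636). For MCAO 72 h replicate 1 this held for Itgb6 (0.703). For MCAO 72 h replicate 2 this held for Nqo1 (0.692). For MCAO 72 h replicate 5 this held for the mean of atrial markers (0.710). For sham 24 h replicate 4 this held for Nr4a3 (0.694). For sham 72 h replicate 6 this held for Kcnd2 (0.706).

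The MCAO effect differed between the times, by the interaction test, for Lce1j (1.96), Tuba4a (1.01), Trdj1 (1.30), Myh7 (2.82), Mir3473d (1.50), an immunoglobulin kappa variable segment (1.29), Gja1 (0.72), more positive at 72 h, and for Nr4a3 (-1.46), Dbp (-1.38), Snora81 (-1.35), Adh1 (-1.27), Higd1a (-1.25), Ctsl (-0.63), more negative (log2). Dbp was also higher by 1.50 (log2) in sham 72 h than in sham 24 h, and lower after MCAO at 72 h (-1.09, limma adjusted p = 0.00908). Of the 958 unnamed identifiers, which the comparisons do not use, 197 passed at 24 h and 19 at 72 h.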

How the results depend on the processing

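Fits without named pairs of arrays, with the receptor component and, for lists, without each array were chosen after the data were examined; the others were planned. Quantile normalization on top, median centring and the mean of identifiers moved next to nothing, as the values were already normalized with nearly 1 row per gene. At 24 h (5237 genes) the count was 3441 with the dim filter, which tests fewer genes, 3259 with array weights, 2194 with only the groups compared and 319 with the receptor component. Elsewhere it stayed within 1.5 times. At 72 h (565) it was 1905 with array weights, 1410 with only the groups compared and 1103 without MCAO 24 h replicates 5 and 6. The median residual SD was 0.116 in the 72 h groups, 0.192 in the 24 h groups and 0.164 over all. The difference between times (430) became 219 with the dim filter, 1079 without MCAO 24 h replicates 5 and 6, 279 without the sham pair and 5 with the receptor component, which shared 0 genes with the 430. The cause was not tested. The sham contrast (5) became 27 with array weights, 3 without the sham pair and 1 with only the groups compared, and the cause was not tested. Lists at 24 h (7) became 1 with an estimated correlation and 12 with fry, and at 72 h (17) became 6 with an estimated correlation. The correlation (0.493) became 0.390 with the receptor component. Leaving out each array gave 4234 to 5867 genes at 24 h, 393 to 821 at 72 h, 197 to 1012 for the difference, 1 to 6 for the sham contrast, 6 to 8 lists at 24 h and 14 to 19 at 72 h. Lists that passed only without single arrays were oxidative stress at 24 h (16 arrays) and, at 72 h, fibroblast (6), sarcomere (3), smooth muscle (2) and hypertrophy (2).

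The replicate numbers did not pair the samples: 3 of 36 same-numbered pairs had residuals correlated above 0.1 (median -0.00459), and 2 of 24 arrays correlated best with their own number. With the number as a block, 4938, 519, 295 and 1 genes passed at 24 h, at 72 h, for the difference and between the sham groups, and 7 and 17 lists passed. Of 304 named-gene results, 217 had passed and 0 of these changed sign under the settings chosen before the data were examined. Of those that had not passed, 2 did at 72 h when 1 array was left out, Bmp10 (0.59, and -0.07 without MCAO 72 h replicate 5) and Stfa2l1 (0.09, and -0.02 without MCAO 72 h replicate 1). Array weights ended 31 calls and added 42, and the block ended 15 and added 3. Leaving out single arrays ended at least once 19 of 130 calls of named genes at 24 h, 19 of 72 at 72 h, 3 of 10 for the difference and 4 of 5 between the sham groups. Dim genes carry no detection call here, so a small change near the floor cannot be told from background.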

Other observations

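The tests of hypotheses in this part were chosen after the result was seen. Gene groups that did not pass as lists held single genes that moved. At 24 h, in the clock list, Cry2 (log2 change 1.09, SE 0.14), Per2 (1.21, SE 0.18) and Cry1 (0.57, SE 0.10) rose. Among apoptosis and p53 targets the survival gene Bcl2l1 (1.17, SE 0.12) and the death receptor gene Fas (1.05, SE 0.15) rose, and at 72 h they rose by 0.88 (SE 0.12) and 0.95 (SE 0.15). Insulin receptor substrate gene Irs2 rose by 1.60 (SE 0.17) and the hexokinase gene Hk2 fell by 0.63 (SE 0.11) at 24 h; Hk2 fell by 0.63 (SE 0.11) at 72 h as well. Among endothelial markers Kdr, the VEGF receptor gene, fell by 0.88 (SE 0.12) at 24 h and fell by 0.68 (SE 0.12) at 72 h, while Rgcc rose by 0.94 (SE 0.13) and 0.68 (SE 0.13). Dpep1, of the fibroblast list, rose by 1.56 (SE 0.16) and 1.36 (SE 0.16), and Myom2, of the sarcomere list, by 0.67 (SE 0.15) and 1.05 (SE 0.15).

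At 24 h the 27 lists that did not pass had camera adjusted p from 0.0503 to 0.991. Their member counts are from the fit of all 24 arrays, in which 21.8% of all genes passed at 24 h. The numbers of members that rose and fell, of those measured, were as follows for response lists: oxidative stress response (6 and 2 of 20), circadian clock (6 and 2 of 17), oxidative phosphorylation (0 and 4 of 31), cell cycle and proliferation (0 and 7 of 31), acute phase and interleukin-6 response (7 and 1 of 25), heat shock response (1 and 2 of 15), natriuretic peptides and hypertrophy programme (0 and 3 of 17) and immediate-early and adrenergic response (7 and 3 of 24). Further response lists were chemokines and leukocyte adhesion (1 and 3 of 24), apoptosis and p53 targets (5 and 3 of 18), endoplasmic reticulum stress (3 and 5 of 21), sarcomere (1 and 3 of 19), interferon response (1 and 1 of 25), polyamine / angiotensin and endothelial stress (0 and 1 of 15), glucose and insulin metabolism (6 and 3 of 22) and hypoxia response (3 and 2 of 17). Among markers of other cells and tissues the numbers were neutrophil (2 and 0 of 15), atrial (2 and 0 of 10), lung / thymus and skeletal muscle contamination (0 and 5 of 19), B cell (1 and 2 of 15), smooth muscle and pericyte (1 and 4 of 15), erythroid and platelet (1 and 2 of 9), fibroblast (1 and 4 of 17), endothelial (5 and 3 of 20), T and NK cell (0 and 2 of 23), Schwann cell / neuronal and epicardial (1 and 2 of 16) and monocyte and macrophage (4 and 1 of 24). With only the groups compared, oxidative stress (adjusted p = 0.0236) and atrial markers (adjusted p = 0.0428) passed, and atrial markers did without MCAO 24 h replicates 5 and 6 (adjusted p = 0.0379). In the limma fit of only these groups, the oxidative phosphorylation members lost their calls: Atp5o (adjusted p = 0.0598), Sdhd (0.103), Ndufa5 (0.169) and Ndufv2 (0.157). So did the heat shock members Hspe1 (0.0519), Hspb7 (0.205) and Dnajb1 (0.172), and the T and NK cell markers Cd8b1 (0.103) and Nkg7 (0.135). The clock members Cry2 (0.000748), Per2 (0.000901) and Cry1 (0.00670) kept theirs.

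At 72 h the 17 lists that did not pass had camera adjusted p from 0.0700 to 0.931. The numbers of members that rose and fell, of those measured, were as follows for response lists: sarcomere (2 and 0 of 19), natriuretic peptides and hypertrophy programme (2 and 0 of 17), apoptosis and p53 targets (5 and 2 of 18) and heat shock response (0 and 1 of 15). Further response lists were hypoxia response (1 and 1 of 17), polyamine / angiotensin and endothelial stress (0 and 0 of 15), glucose and insulin metabolism (0 and 1 of 22) and circadian clock (1 and 1 of 17). Among markers of other cells and tissues the numbers were fibroblast (2 and 2 of 17), smooth muscle and pericyte (1 and 1 of 15), erythroid and platelet (0 and 0 of 9), Schwann cell / neuronal and epicardial (0 and 0 of 16), atrial (0 and 0 of 10), endothelial (2 and 3 of 20), lung / thymus and skeletal muscle contamination (0 and 1 of 19), neutrophil (0 and 0 of 15) and T and NK cell (0 and 0 of 23). Without MCAO 24 h replicates 5 and 6, sarcomere (adjusted p = 0.0285) and heat shock (adjusted p = 0.0439) passed at 72 h, as they did with only the groups compared (adjusted p = 0.0401 and 0.00826).

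For the difference between times, camera passed for natriuretic peptides and hypertrophy programme (upward, adjusted p = 0.0467, adjusted p = 0.930 with an estimated correlation), interferon response (downward, adjusted p = 0.0147, adjusted p = 0.930 with an estimated correlation), endoplasmic reticulum stress (upward, adjusted p = 0.0147, adjusted p = 0.930 with an estimated correlation). Between the sham groups it passed, besides the clock list, for fatty acid use and PPAR targets (downward, adjusted p = 0.000783, adjusted p = 0.574 with an estimated correlation), interferon response (upward, adjusted p = 0.00109, adjusted p = 0.655 with an estimated correlation). It also passed for extracellular matrix and collagen (downward, adjusted p = 0.0304, adjusted p = 0.655 with an estimated correlation), oxidative phosphorylation (upward, adjusted p = 0.0484, adjusted p = 0.655 with an estimated correlation), monocyte and macrophage markers (upward, adjusted p = 0.0455, adjusted p = 0.655 with an estimated correlation), fibroblast markers (upward, adjusted p = 0.000607, adjusted p = 0.574 with an estimated correlation), atrial markers (upward, adjusted p = 0.00112, adjusted p = 0.574 with an estimated correlation). Without MCAO 24 h replicates 5 and 6, the hypertrophy list lost its call for the difference between times (adjusted p = 0.198), as did oxidative phosphorylation (adjusted p = 0.0658) and monocyte and macrophage markers (adjusted p = 0.0635) between the sham groups.

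Clock genes that had not passed over all genes were used to ask whether the sham groups may have been collected at different times of day. Per2, Nr1d1, Nr1d2, Tef, Hlf, Ciart and Bhlhe41 less Clock and Nfil3 were higher by 0.80 (log2) in sham 72 h than in sham 24 h (exact permutation test, two-sided, p = 0.00433, adjusted p = 0.0195 over 18 tests). These genes come from the clock list, which had 9 members up and 3 down of 17 there, adjusted over the list alone. The index thus largely restates that difference in the same arrays and is no separate support for the hypothesis. The collection times are not given in the sources used here. The same index differed by 0.26 between MCAO and sham at 24 h (exact permutation p = 0.197) and by -0.25 at 72 h (exact permutation p = 0.152).

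Within MCAO 24 h, Gm10051, chosen after its values were seen, was between 6.88 and 8.08 (log2) in replicates 1 to 4 and at 12.15 and 11.29 in replicates 5 and 6. In the other groups it was between 11.11 and 12.21. Pabpc1 and Hspa8, also chosen after their values were seen, went the other way. Pabpc1 was at 6.33 and 8.76 in replicates 5 and 6 and between 10.07 and 10.90 in replicates 1 to 4, and elsewhere between 10.64 and 11.42. Hspa8 was at 10.73 and 7.32 in replicates 5 and 6, between 12.26 and 12.32 in replicates 1 to 4, and elsewhere between 12.22 and 12.73.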
